A study of Homo sapiens with 12 samples.

How the data were processed

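RNA from MDA-MB-231 and HCC70 cells, kept for 72 hours with JQ1 at 500 nM or with vehicle (DMSO at 0.1%), was labelled (150 ng per sample) and hybridised to 12 Human Gene 2.0 ST arrays, 3 in each of 4 groups. The values used are log2 signals of transcript clusters as deposited; RMA, oligo and limma are named in the submitters' processing notes, without versions. The genome build is not given in the sources used here, so no coordinates are printed. Over the genes tested the array medians lay between 6.16 and 6.26 and the upper quartiles between 7.52 and 7.77, and at most 0.229% of values were identical in any pair of arrays. Columns of other series were checked for and 0 were found.

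The table held 53617 transcript clusters. Of these, 16098 had 1 gene symbol in the annotation, 0 had several and 37519 had none, and clusters without a symbol entered only the test over all clusters. For the 779 genes with more than 1 cluster the cluster with the highest mean over the 12 arrays was kept, which left 14884 genes. SERPINI1 and CDKN1A, and the histone list (0 of 36 genes measured), were not analysed here. No filter on dim genes was applied, and a change or difference that ends at a level below the lower quartile of the genes on those arrays is read as a lower bound, whose SE covers the spread of arrays only. Where such levels limit the falls seen in both lines, the difference of the JQ1 effects is a bound in neither direction.

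Group means were fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, with neither trend nor robust moderation; statmod 1.5.0). The contrasts were JQ1 minus vehicle in each line, the difference of these effects (HCC70 minus MDA-MB-231), and HCC70 vehicle minus MDA-MB-231 vehicle. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over all genes tested, and genes with an adjusted p under 0.05 were called. A standard error (SE) is that of the limma coefficient with the moderated variance, and a standard deviation (SD) that of 3 arrays. Expected overlaps are the product of the list lengths over the number of genes tested.

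Named genes followed a rule. For each JQ1 comparison it took the 8 largest rises and the 8 largest falls among called genes whose 3 JQ1 arrays all lay on one side of the 3 vehicle arrays, 13 fixed readouts (10 measured), and up to 2 members with the smallest p in each direction of a described list. For the difference of the effects it took the 6 most positive and 6 most negative genes, and for the vehicle-treated lines 5 in each direction. Of 34 gene lists, 33 had measured members and were tested with camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists of a contrast, and again with an estimated correlation and with fry. Each list's members were also adjusted over the list alone. The median, mean and test of a list differed in sign for 12 lists in MDA-MB-231, 5 in HCC70, 3 for the difference and 6 between the vehicle-treated lines, 0 of which camera called. The comparisons, tests, lists, naming rule and alternatives were chosen before the data were examined, except where stated.

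The alternatives were the replicate number as a block, each line fitted alone, a variance trend with robust moderation, genes above the median level, the mean of a gene's clusters, all transcript clusters, quantile normalization, centring on array medians, array weights, a log2 change of at least 1, and leaving out each array in turn. A fit without the 3 arrays numbered 3 that stood apart (MDA-MB-231 vehicle, MDA-MB-231 JQ1 and HCC70 JQ1) was added after seeing the data. The replicate numbers were checked as pairs by the correlation, across genes, of the deviations of a vehicle and a JQ1 array from their group means. In MDA-MB-231 arrays with the same number correlated at 0.155, 0.121 and 0.362, and arrays with different numbers at -0.250 to 0.121. Only number 3 stood clearly apart, since vehicle replicate 2 correlated with JQ1 replicate 1 as closely as with JQ1 replicate 2 (0.121). With the number as a block 4210 genes were called in place of 4139.

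The procedure was tested on simulated data with 14884 genes of which 200 changed. Changes of 0.5, 1 and 2 on the log2 scale were recovered in 56.3%, 89.6% and 100% of cases for JQ1 in MDA-MB-231, in 45.3%, 90.0% and 100% for HCC70, in 18.0%, 78.5% and 100% for the difference of the effects, and in 45.3%, 83.6% and 98.6% between the lines. False calls made up 5.71%, 3.66%, 6.99% and 4.49% of the calls. Far fewer genes changed in the simulation than were called in the data, and its noise was independent between genes. These rates check the procedure and need not hold for the comparisons below.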

Results

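Gene expression was measured on 12 Human Gene 2.0 ST arrays in MDA-MB-231 and HCC70, a pair of human triple-negative breast cancer cell lines. Each line was kept for 72 hours with JQ1 at 500 nM or with the vehicle (DMSO at 0.1%). JQ1 is a small molecule that occupies the acetyl-lysine pockets of the BET bromodomain proteins, among them BRD2 and BRD3, and displaces them from chromatin. There were 3 arrays in each of 4 groups, and their number limits the precision of every value. The labels do not say that the 3 arrays of a group came from separate cultures, so the p-values measure only the spread between these samples. Arrays of 1 group correlated at r = 0.989 to 0.995 over the 14884 genes tested, arrays of the same line under the other treatment at 0.962 to 0.978, and arrays of different lines at 0.875 to 0.90. In a principal component analysis the first component held 73.9% of the variance and parted the cell lines, and the next held 12.8% and parted JQ1 from vehicle in both lines.

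The first comparison asked which genes JQ1 changed in MDA-MB-231. All 35 mitotic genes measured fell, as did 23 of 25 DNA replication genes, 12 of 12 homologous recombination genes, 16 of 27 interferon response genes and 8 of 15 fatty acid synthesis genes. Camera called these lists, but with an estimated correlation it called 0 lists in this line (adjusted p = 0.061 for mitotic, 0.084 for replication, repair and interferon response and 0.24 for fatty acid synthesis genes). The long noncoding RNA UCA1 had the largest rise, 10.4-fold (log2 change 3.37 ± 0.076 SE, n = 3 arrays per group), and LAPTM5, a lysosomal membrane protein best known from blood cells, the largest fall measured, 11.4-fold (log2 change -3.51 ± 0.15). With limma and Benjamini-Hochberg adjustment, 4139 of 14884 genes changed at an adjusted p threshold of 0.05, of which 1607 rose and 2532 fell. Among the 648 genes with a log2 change of at least 1 in size, 119 rose and 529 fell.

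The other genes with large rises in MDA-MB-231 were EFR3B, a plasma membrane scaffold of a lipid kinase, at 9.89-fold (log2 8.75 ± 0.060 SD under JQ1 against 5.45 ± 0.20), the basic helix-loop-helix factor ATOH8 at 7.01-fold, the imprinted, retrotransposon-derived gene PEG10 at 6.95-fold, the calcitonin receptor CALCR at 5.31-fold, the dynamin DNM3 at 4.66-fold, the protease inhibitor TFPI2 at 4.54-fold and RFESD at 4.52-fold. The other large falls were in CLIC6, of the chloride intracellular channel family (9.09-fold), the mitotic kinase PBK (9.08-fold), RTKN2 (8.44-fold), the secreted scavenger-receptor glycoprotein DMBT1 (7.93-fold), the cytokine receptor IL7R (7.79-fold), the long-chain acyl-CoA synthetase ACSL5 (7.46-fold) and DEPDC1 (7.32-fold). RTKN2, DMBT1 and IL7R, at 4.34, 4.59 and 3.63 under JQ1, lay below the lower quartile of the genes on those arrays, so their folds are read as lower bounds. The naming rule took only called genes whose 3 JQ1 arrays lay on one side of the 3 vehicle arrays, so that separation is no added support. The largest adjusted p among these 16 genes was 9.4e-06 for RFESD (limma with Benjamini-Hochberg adjustment).

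Direct readouts of BET inhibition moved as follows in MDA-MB-231. BRD2, a target of JQ1, rose 1.82-fold (log2 change 0.86 ± 0.089), and HEXIM1, an inhibitor of the elongation kinase P-TEFb that is often used as a marker of BET inhibitor exposure, rose 1.51-fold (log2 change 0.59 ± 0.13, limma adjusted p = 0.0036). The transcription factor MYC fell by 0.41 ± 0.10 on the log2 scale (adjusted p = 0.0076), and FOSL1, a FOS-family subunit of AP-1, fell by 1.47 ± 0.15. BRD3 differed by -0.14 ± 0.078, which did not pass (adjusted p = 0.22). SERPINI1 and CDKN1A were not analysed here. Over the 14 measured genes of the BET and P-TEFb list, 4 rose and 1, the elongation factor subunit NELFCD, fell, with the same counts adjusted over the list alone, and the list as a whole was not called (camera adjusted p = 0.57).

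Mitotic genes had the smallest camera p in MDA-MB-231. All 35 measured members of the list of mitotic kinases, spindle and cytokinesis genes fell, over all genes and adjusted over the list alone, with a median log2 change of -2.00 (quartiles -2.36 and -1.68). For mitotic genes camera gave adjusted p = 5.3e-41, and adjusted p = 0.061 with an estimated correlation. Cyclin A2, encoded by CCNA2, fell by 2.46 ± 0.085, the topoisomerase TOP2A by 2.28 ± 0.080, and the Aurora kinases AURKA and AURKB by 2.00 ± 0.095 and 1.98 ± 0.086. Among regulators of these genes, the transcription factors FOXM1 and MYBL2 fell by 2.19 ± 0.096 and 1.95 ± 0.10, and the MuvB subunit LIN9 by 1.31 ± 0.11. In the list of MuvB, B-MYB and FOXM1 regulators, 9 of 13 measured genes fell and 0 rose by limma, 9 adjusted over the list alone, with a median of -0.53. For these regulators camera gave adjusted p = 6.1e-05, and adjusted p = 0.29 with an estimated correlation.

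**Figure D1:**
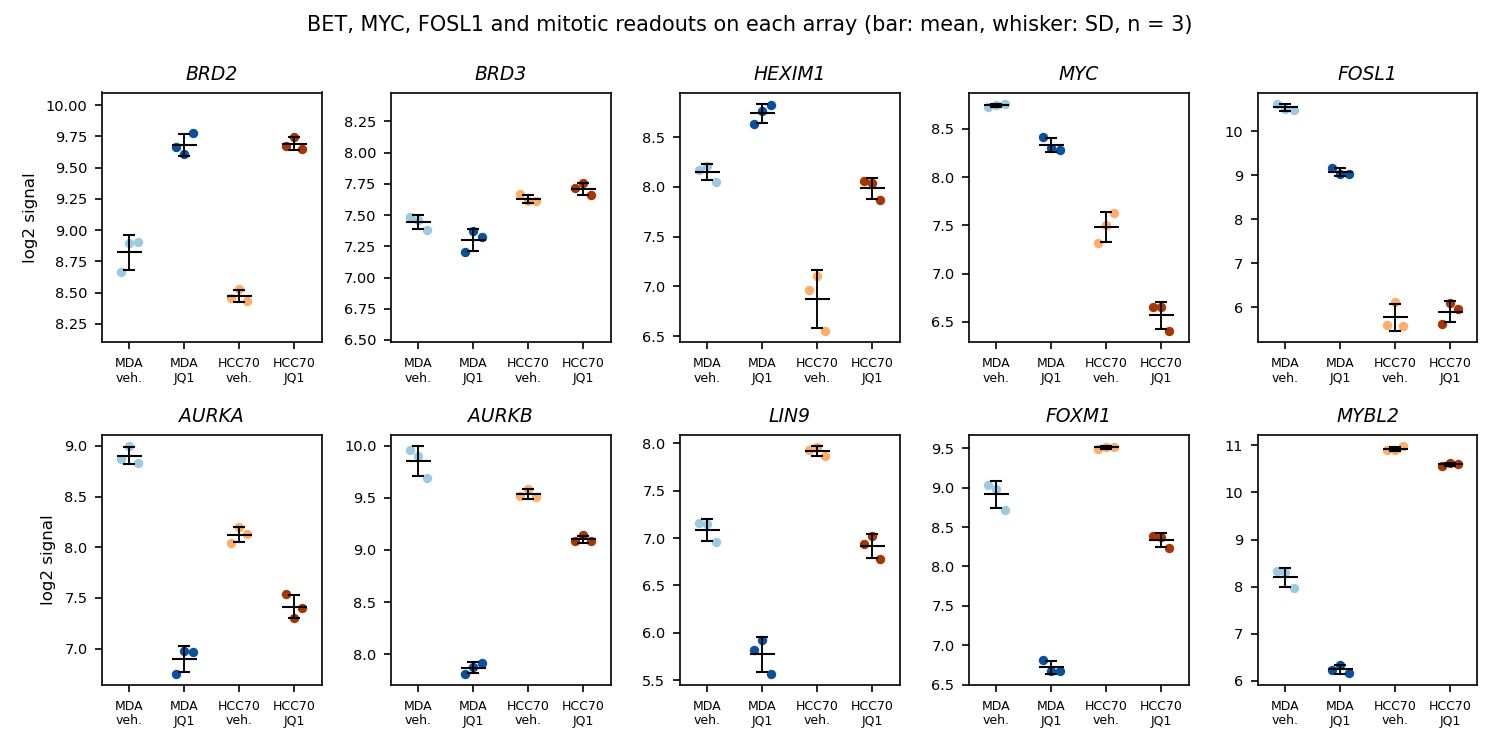
Log2 signal of 10 readout genes on each of the 12 arrays, by group (veh., vehicle; points, single arrays; bar and whisker, mean and SD, n = 3). AURKA was at 8.90 in vehicle-treated and 6.90 in JQ1-treated MDA-MB-231, and at 8.13 and 7.41 in HCC70, while FOSL1 was at 10.54 and 9.07 in MDA-MB-231 and at 5.77 and 5.89 in HCC70.

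Genes of DNA synthesis and repair fell in MDA-MB-231 as well. Of 25 measured genes of DNA replication and nucleotide synthesis, 23 fell, and 25 did when adjusted over the list alone, with a median of -1.10. For replication genes camera gave adjusted p = 3.5e-20, and adjusted p = 0.084 with an estimated correlation. The ubiquitin-ligase subunit DTL fell by 1.67 ± 0.085 and the replication factor MCM10 by 1.97 ± 0.11. All 12 measured genes of homologous recombination and Fanconi repair fell, 12 adjusted over the list alone, with a median of -1.02. For repair genes camera gave adjusted p = 6.7e-10, and adjusted p = 0.084 with an estimated correlation. RAD51AP1 fell by 2.05 ± 0.11 and the helicase BRIP1 by 1.76 ± 0.093. In the list of G1 cyclins, CDKs and E2F genes, 14 of 17 fell, 14 adjusted over the list alone, with a median of -0.93. For G1 and E2F genes camera gave adjusted p = 4.5e-09, and adjusted p = 0.084 with an estimated correlation. E2F3 fell by 1.85 ± 0.092 and E2F8 by 1.95 ± 0.10. Of 23 measured ribosome biogenesis genes, 16 fell, 17 adjusted over the list alone, with a median of -0.42. For ribosome biogenesis camera gave adjusted p = 1.1e-06, and adjusted p = 0.13 with an estimated correlation. The members with the smallest p were TCOF1, a cofactor of ribosomal RNA synthesis, which fell by 0.97 ± 0.099, and WDR12, which fell by 0.70 ± 0.090.

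Camera also called stress, interferon and lipid lists downward in MDA-MB-231. In the list of the unfolded protein response and amino acid stress, 10 of 16 genes fell and 1 rose, with the same counts adjusted over the list alone and a median of -0.68. For this stress list camera gave adjusted p = 1.6e-05, and adjusted p = 0.084 with an estimated correlation. The members with the smallest p were PSAT1, an enzyme of serine synthesis, which fell by 1.94 ± 0.10, and the lipoprotein receptor VLDLR, which fell by 1.17 ± 0.080. Of 27 interferon response genes, 16 fell and 1 rose, the same counts adjusted over the list alone, with a median of -0.44. For interferon response genes camera gave adjusted p = 7.5e-05, and adjusted p = 0.084 with an estimated correlation. The apoptosis-associated factor XAF1 fell by 1.92 ± 0.13 and the antiviral membrane protein IFITM1 by 1.55 ± 0.12, whereas the transcription factor IRF7 rose by 0.85 ± 0.097. Of 15 fatty acid synthesis genes, 8 fell and 1, FADS3, rose, also adjusted over the list alone. For fatty acid synthesis camera gave adjusted p = 0.00083, and adjusted p = 0.24 with an estimated correlation. The desaturase SCD and the synthase FASN fell by 1.55 ± 0.079 and 0.99 ± 0.087. Cholesterol synthesis and uptake genes fell in 11 of 17 cases, 1 rose, with the same counts adjusted over the list alone. For cholesterol genes camera gave adjusted p = 0.0043, and adjusted p = 0.32 with an estimated correlation and 0.090 among genes above the median level. INSIG1, a brake on sterol synthesis, fell by 1.42 ± 0.086.

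Inflammatory and mesenchymal genes were lower in part. Of 21 NF-kB and inflammatory cytokine genes, 7 fell and 0 rose by limma, 7 adjusted over the list alone. For inflammatory genes camera gave adjusted p = 0.013, and adjusted p = 0.084 with an estimated correlation and 0.13 among genes above the median level. The adhesion receptor ICAM1 had a log2 change of -2.41 ± 0.13 and the chemokine CXCL8 one of -1.39 ± 0.096, a bound with JQ1 at 3.55. Of 16 mesenchymal genes, 7 fell and 1, FBN1, rose, also adjusted over the list alone. VIM, which encodes vimentin, did not pass on the cluster kept (log2 change 0.15). It rose on its other clusters, of similar level, by 0.72 and 0.89 (limma adjusted p = 2.4e-05 and 0.0046 over clusters with a gene symbol). For mesenchymal genes camera gave adjusted p = 0.018, and adjusted p = 0.084 with an estimated correlation. Fibronectin, FN1, fell 2.64-fold and the collagen cross-linking enzyme LOX fell by 1.83 ± 0.18. In total 12 of the 33 lists tested were called in MDA-MB-231, all 12 downward, and 0 were called by camera with an estimated correlation, where 9 had an unadjusted p under 0.05; fry, which asks only whether a list's own genes move one way, called 19. Among lists of other cell types, 1 of 8 blood cell markers fell (CSF1R, by 0.45 ± 0.14, a call that ended with arrays centred on their medians, adjusted p = 0.054, without MDA-MB-231 vehicle replicate 2, adjusted p = 0.14, or any 1 of the 3 JQ1 arrays, adjusted p = 0.064 to 0.079), and adjusted over the list alone 0 did by limma, while 0 of 10 stromal, endothelial and adipocyte markers changed by limma in MDA-MB-231, also adjusted over the list alone.

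Limits of the MDA-MB-231 comparison were that the share of falls depended on the scale, 61.2% of the called genes as deposited and 48.9% (2091 genes lower, 2185 higher) after centring each array on its median, and that HEXIM1 missed the threshold without the 3 arrays numbered 3 that stood apart (adjusted p = 0.050).

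The next comparison asked which genes JQ1 changed in HCC70. Of 27 interferon response genes 20 fell, of 35 mitotic genes 28 fell, and of 20 AP-1 and immediate early genes 9 rose and 2 fell. Camera called these 3 lists, and with an estimated correlation the adjusted p was 0.031 for interferon response genes, 0.23 for mitotic genes and 0.17 for AP-1 genes. The largest fall measured was in CP, which encodes the copper carrier ceruloplasmin, 22.4-fold (log2 change -4.49 ± 0.16 SE, n = 3 arrays per group), and the largest rise in TFPI2, 6.68-fold (2.74 ± 0.087). With limma and Benjamini-Hochberg adjustment, 3229 of 14884 genes changed, 1366 upward and 1863 downward, and of the 380 with a log2 change of at least 1 in size, 89 rose and 291 fell.

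The other large rises in HCC70 were in AMIGO3 (4.89-fold), IQCN (4.64-fold), PEG10 (4.50-fold), the proprotein convertase PCSK5 (3.91-fold), the cytoskeletal linker epiplakin, EPPK1 (3.90-fold), the zinc finger repressor ZNF10 (3.40-fold) and the matricellular protein CCN2 (3.33-fold). The other large falls were in the interferon-induced gene IFI44L (18.5-fold), the acyltransferase-like GLYATL2 (15.6-fold), the toll-like receptor relative CD180 (12.8-fold), the adhesion molecule CEACAM6 (11.3-fold), the lysosomal protease cathepsin S, CTSS (log2 change -3.45 ± 0.11), IFITM1 (10.9-fold) and DMBT1 (10.5-fold). IFI44L and CD180, at 3.54 and 4.43 under JQ1, lay below the lower quartile of the genes on those arrays, so their folds are read as lower bounds. CEACAM6 had the widest spread of these large falls, 7.47 ± 0.74 (SD) under JQ1 against 10.97 ± 0.022 in vehicle. Of the readouts of BET inhibition, BRD2 rose 2.32-fold (log2 change 1.22 ± 0.089), HEXIM1 rose 2.16-fold (1.11 ± 0.13) and MYC fell by 0.92 ± 0.10, while FOSL1 (0.13 ± 0.15, limma adjusted p = 0.66) and BRD3 (0.08 ± 0.078, adjusted p = 0.59) did not pass. HEXIM1 has another, dimmer transcript cluster with a log2 change of -0.55 (adjusted p = 0.25), and the mean of both clusters, 0.28, did not pass (adjusted p = 0.37).

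Interferon response genes fell in HCC70 in 20 of 27 cases and rose in 1, with the same counts adjusted over the list alone and a median of -0.82 (quartiles -1.74 and -0.31; camera adjusted p = 6.9e-13). This was the 1 list of the 12 called that held with an estimated correlation (adjusted p = 0.031 with an estimated correlation). IFI44L fell by at least 4.21, a lower bound as above, and IFITM1 by 3.45 ± 0.12, and IRF7 rose by 0.56 ± 0.097. In the NF-kB and inflammatory cytokine list 4 of 21 genes fell, 4 adjusted over the list alone, and the list was not called (camera adjusted p = 0.098); among them the chemokine CCL2 fell by 2.08 ± 0.29, a bound with JQ1 at 4.31, and CCL5 by 1.15 ± 0.12.

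Of the 35 mitotic genes 28 fell in HCC70, 30 adjusted over the list alone, with a median of -0.50 (quartiles -0.72 and -0.32). For mitotic genes in HCC70 camera gave adjusted p = 7.3e-15, and adjusted p = 0.23 with an estimated correlation. CCNA2 fell by 1.01 ± 0.085, the spindle midzone protein PRC1 by 1.11 ± 0.094, AURKA by 0.71 ± 0.095 and AURKB by 0.43 ± 0.086. FOXM1 fell by 1.18 ± 0.096 and LIN9 by 1.01 ± 0.11. MYBL2 fell by 0.33 ± 0.10 (limma adjusted p = 0.033), a call that ended without any 1 of the 6 HCC70 arrays (adjusted p = 0.067 to 0.11) and with arrays centred on their medians (-0.26, adjusted p = 0.077). Of 13 MuvB, B-MYB and FOXM1 regulators 5 fell and 2 rose, 6 and 2 adjusted over the list alone, and the list was not called (camera adjusted p = 0.21). In the list of G1 cyclins, CDKs and E2F genes 6 of 17 fell, 8 adjusted over the list alone. For G1 and E2F genes in HCC70 camera gave adjusted p = 0.0027, and adjusted p = 0.23 with an estimated correlation. E2F2 fell by 2.06 ± 0.11 and E2F8 by 0.97 ± 0.10. Of 12 homologous recombination and Fanconi repair genes 4 fell, 5 adjusted over the list alone. For repair genes in HCC70 camera gave adjusted p = 0.034, and adjusted p = 0.55 with an estimated correlation. The call ended without HCC70 JQ1 replicate 3 (adjusted p = 0.14) or vehicle replicate 2 (0.066), without the 3 arrays numbered 3 (0.13) and among genes above the median level (0.061). DNA replication and nucleotide synthesis genes went both ways, with 8 of 25 falling, such as MCM5 by 0.58 ± 0.096, and 2 rising, CLSPN by 0.52 ± 0.14 and CDC6 by 0.40 ± 0.11; adjusted over the list alone 10 fell and 2 rose, and the list was not called (camera adjusted p = 0.056). The call of CLSPN ended without HCC70 JQ1 replicate 1, vehicle replicate 1 or vehicle replicate 2 (adjusted p = 0.056 to 0.058), and with the mean of a gene's clusters (0.067), and that of CDC6 without JQ1 replicate 1, JQ1 replicate 2 or vehicle replicate 1 (adjusted p = 0.068 to 0.081).

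**Figure D2:**
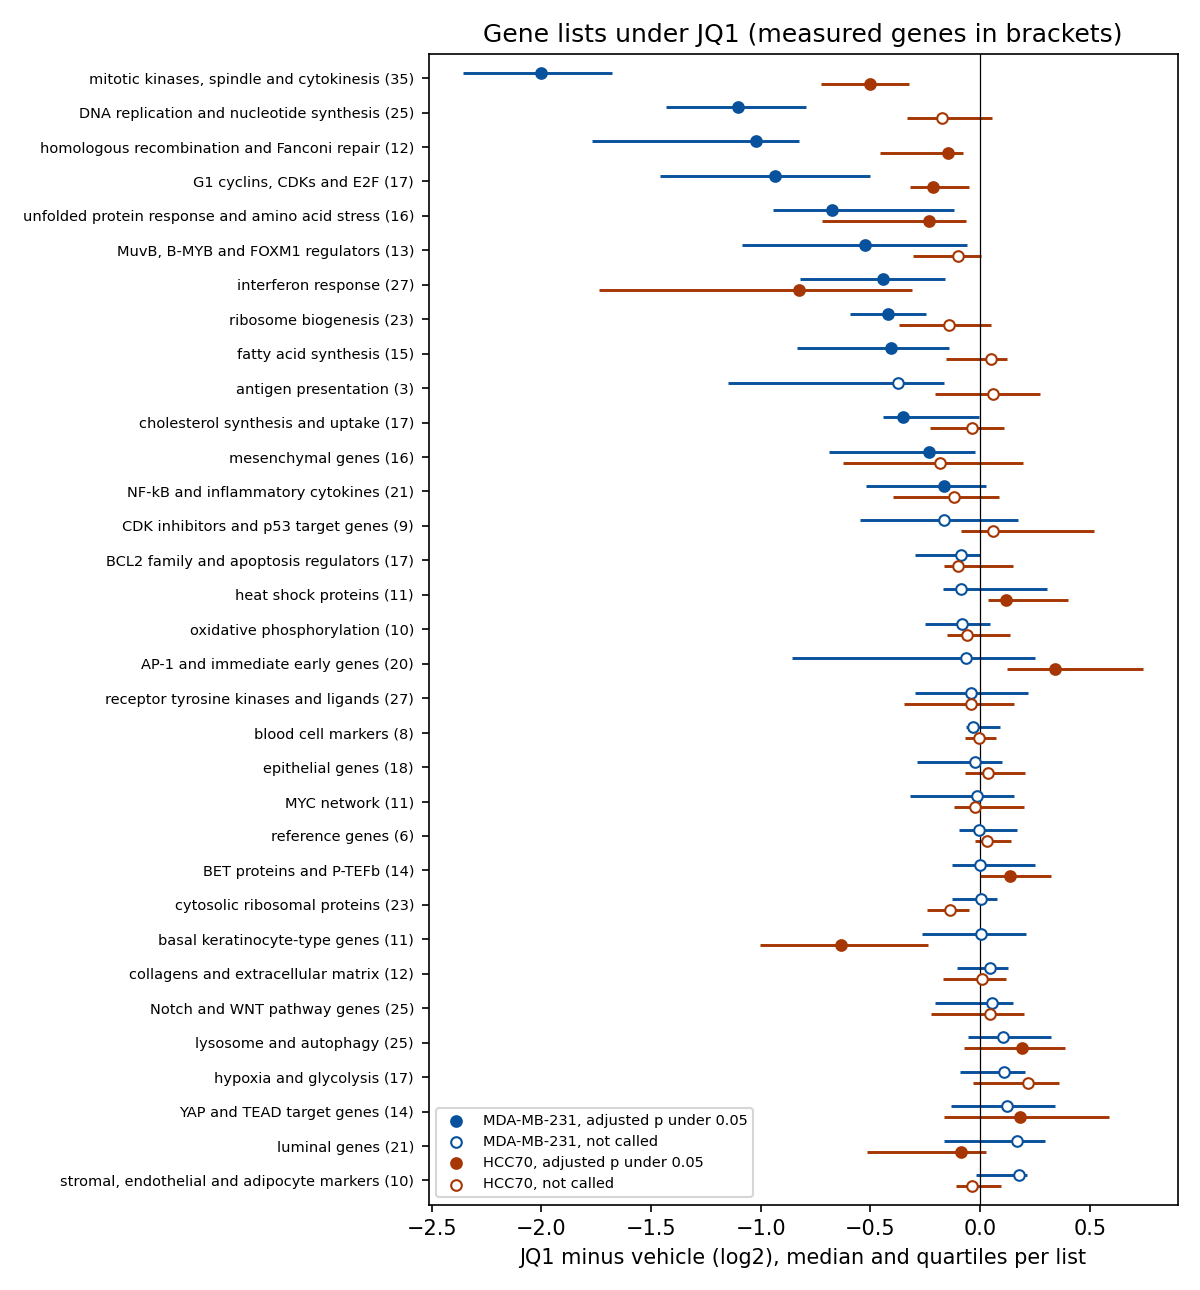
Median log2 change under JQ1 (point) and its quartiles (line) for the 33 gene lists tested, in MDA-MB-231 (blue) and HCC70 (brown); filled points passed camera at an adjusted p threshold of 0.05. Mitotic genes lay at -2.00 in MDA-MB-231 and -0.50 in HCC70, and interferon response genes at -0.44 and -0.82.

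Of 20 AP-1 and immediate early genes measured in HCC70, 9 rose and 2 fell, and 11 rose and 2 fell when adjusted over the list alone, with a median of 0.34. For AP-1 genes camera gave adjusted p = 0.00016, and adjusted p = 0.17 with an estimated correlation. EGR1 rose by 1.34 ± 0.13 and JUND by 1.26 ± 0.085, whereas ETV4 and the signalling antagonist SPRY2 fell by 0.82 ± 0.18 and 0.43 ± 0.086. Lysosome and autophagy genes rose in 9 of 25 cases and fell in 2, and in 10 and 3 adjusted over the list alone. For lysosome genes camera gave adjusted p = 0.0027, and adjusted p = 0.23 with an estimated correlation. The sialidase NEU1 rose by 0.92 ± 0.087 and ATG2A by 0.78 ± 0.087. Of 14 YAP and TEAD target genes 6 rose and 2 fell, 7 and 3 adjusted over the list alone. For YAP target genes camera gave adjusted p = 0.027, and adjusted p = 0.27 with an estimated correlation. CRIM1 rose by 1.10 ± 0.079; the list's call ended with the replicate number as a block (adjusted p = 0.060), with HCC70 fitted alone (0.058) and without the 3 arrays numbered 3 (0.056). Of 11 heat shock genes 3 rose and 0 fell by limma, also adjusted over the list alone. For heat shock genes camera gave adjusted p = 0.027, and adjusted p = 0.36 with an estimated correlation and 0.061 among genes above the median level. Among them HSPB1 rose by 0.49 ± 0.071 and HSPA1A by 0.53 ± 0.084, whose probes may also read its near-identical copy HSPA1B. HSPA1B, at 0.43, is another of the 3 genes that rose. The count and the camera call may therefore hold the same signal more than once. In the BET and P-TEFb list 4 of 14 genes rose and 1, NELFCD, fell, and 7 rose and 2 fell adjusted over the list alone. For BET list genes camera gave adjusted p = 0.034, and adjusted p = 0.27 with an estimated correlation. The call ended without HCC70 JQ1 replicate 2 (adjusted p = 0.074) or vehicle replicate 2 (0.060). It also ended with the replicate number as a block (adjusted p = 0.060), with HCC70 fitted alone (0.058), with the mean of a gene's clusters (0.072) and among genes above the median level (0.061).

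Of 11 basal keratinocyte-type genes measured in HCC70 6 fell and 0 rose by limma, and 7 fell and 1 rose adjusted over the list alone, with a median of -0.63. For basal genes camera gave adjusted p = 0.0027, and adjusted p = 0.23 with an estimated correlation and 0.49 among genes above the median level. The desmosomal cadherin DSG3 fell by 1.64 ± 0.14 and TRIM29 by 0.98 ± 0.12. Of 21 luminal genes 8 fell and 3 rose, also adjusted over the list alone. For luminal genes camera gave adjusted p = 0.034, and adjusted p = 0.23 with an estimated correlation. The receptor kinase KIT fell by 3.23 ± 0.20, while the simple-epithelium keratins KRT18 and KRT8 rose by 0.85 ± 0.091 and 0.45 ± 0.11, and leaving out HCC70 JQ1 replicate 1 ended the list's call (adjusted p = 0.067). The call of the luminal list also ended with the replicate number as a block (adjusted p = 0.051), with array weights (0.063), with a variance trend (0.056) and among genes above the median level (0.58). In the list of the unfolded protein response and amino acid stress 6 of 16 genes fell and 2 rose, 7 and 2 adjusted over the list alone. For stress genes in HCC70 camera gave adjusted p = 0.0052, and adjusted p = 0.23 with an estimated correlation. XBP1 fell by 1.12 ± 0.085 and PSAT1 by 1.15 ± 0.10, and the stress-induced factor ATF3 rose by 0.94 ± 0.13. Of 8 blood cell markers 1, CD68, rose by 0.82 ± 0.074 and 1, CD14, fell by 0.38 ± 0.096, also adjusted over the list alone, and the call of CD14 ended without HCC70 JQ1 replicate 2 or vehicle replicate 2 (adjusted p = 0.060 and 0.061). Of 10 stromal, endothelial and adipocyte markers 1 fell, the pericyte gene RGS5, by 0.42 ± 0.093, also adjusted over the list alone.

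Limits of the HCC70 comparison were that array weights, which gave 1 JQ1 array far more weight than the rest (4.69 for replicate 2), raised the count to 5110 genes, and that 57.7% of the called genes fell as deposited but 43.9% (1505 genes lower, 1925 higher) after centring each array on its median.

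A further comparison asked how far the lines responded alike, from the overlap of calls and from the difference of the JQ1 effects, taken as the effect in HCC70 minus that in MDA-MB-231. JQ1 changed 1634 genes in the same direction in both lines, 609 upward and 1025 downward, where independent lists of these lengths would share 464 (147 and 317), and changed 168 in opposite directions, where independent lists would share 433. Across the 14884 genes the changes in the lines correlated at Pearson r = 0.422 and Spearman rho = 0.383, a description across genes, which are not independent replicates; no arrays are shared between both comparisons. Large shared rises included TFPI2 (log2 2.18 ± 0.087 in MDA-MB-231 and 2.74 ± 0.087 in HCC70) and PEG10 (2.80 ± 0.11 and 2.17 ± 0.11), and large shared falls ACSL5 (-2.90 ± 0.11 and -3.16 ± 0.11) and DMBT1 (-2.99, a bound as above, in MDA-MB-231 and -3.39 ± 0.13 in HCC70). Other shared changes, chosen after their values were seen, were the rises of the triglyceride lipase PNPLA2 (1.22 ± 0.079 and 1.41 ± 0.079) and of the reductase DCXR (1.42 ± 0.089 in both), and the falls of the double-stranded RNA sensor TLR3 (-2.27 ± 0.17, a bound with JQ1 at 4.64, and -2.70 ± 0.17) and the interferon-induced GTPase GBP3 (-1.99 ± 0.14 and -1.88 ± 0.14).

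**Figure D3:**
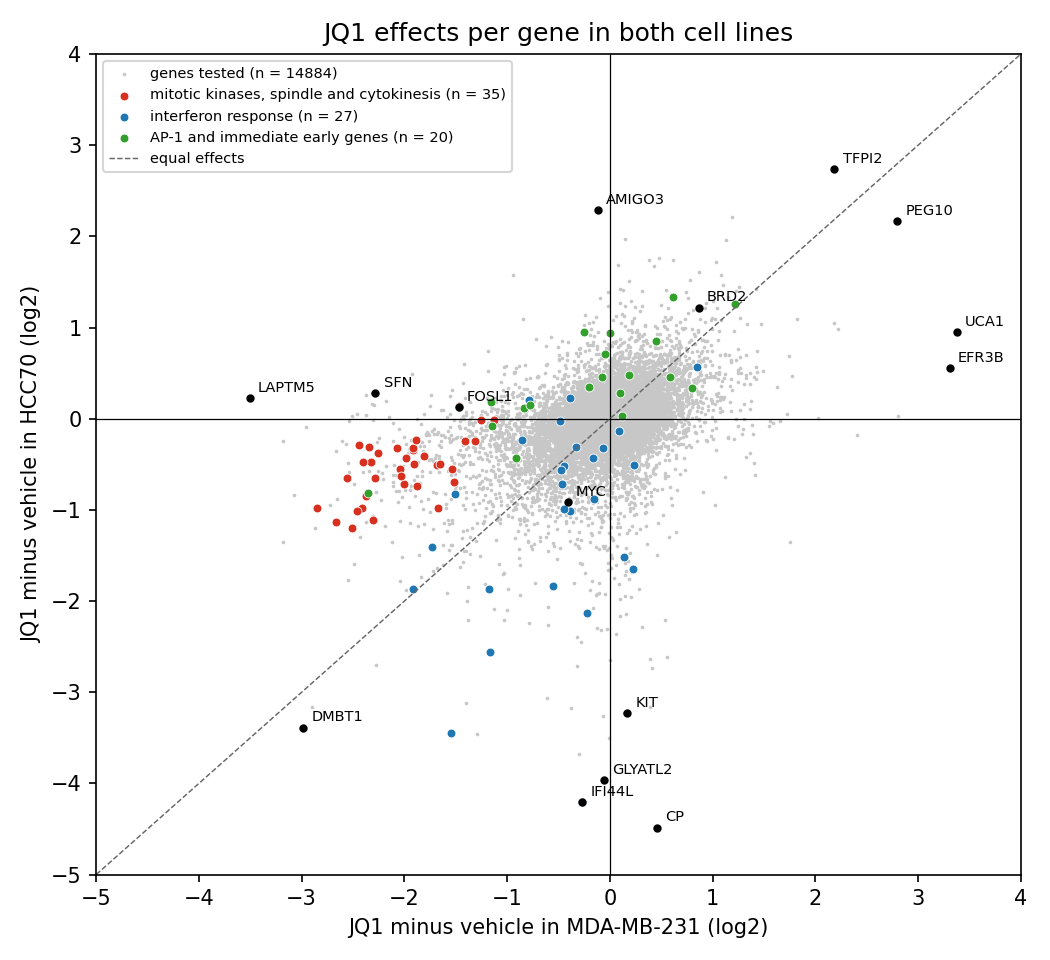
Log2 change under JQ1 of each of the 14884 genes tested in MDA-MB-231 (horizontal) against HCC70 (vertical), with 3 gene lists in colour and 15 named genes in black; the dashed line marks equal effects. The 35 mitotic genes lie left of the dashed line, with medians of -2.00 and -0.50, and CP, IFI44L and GLYATL2 lie at the lower edge with changes of -4.49, -4.21 and -3.96 in HCC70.

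The JQ1 effect differed between the lines for 2228 genes by limma with Benjamini-Hochberg adjustment (1342 differences positive and 886 negative), 1348 of them with the larger change in MDA-MB-231 and 879 in HCC70. Of these genes 364 had been called in the same direction in both lines, 168 in opposite directions, 971 in MDA-MB-231 but not in HCC70, 643 in HCC70 but not in MDA-MB-231, and 82 in neither. The 6 most negative differences were those of CP (-4.94 ± 0.22), IFI44L (-3.93 ± 0.18), GLYATL2 (-3.91 ± 0.26), the transport ATPase ATP13A5 (-3.55 ± 0.31), CEACAM6 (-3.49 ± 0.37) and KIT (-3.40 ± 0.28). All 6 were low in vehicle-treated MDA-MB-231, from 3.32 for GLYATL2 to 4.71 for KIT, where the lower quartile of genes on those arrays was 4.73 to 4.84, and IFI44L and ATP13A5 were also below the lower quartile in JQ1-treated HCC70, at 3.54 and 4.40. These differences are therefore read without an order. Low signals limited the falls of IFI44L and ATP13A5 seen in both lines, so their differences are bounds in neither direction. The 6 most positive differences were those of LAPTM5 (3.73 ± 0.21), CLIC6 (2.94 ± 0.26), IL7R (2.88 ± 0.21), the kinase gene CDK15 (2.64 ± 0.22), the cytokine receptor subunit CRLF2 (2.60 ± 0.21) and the cell-cycle inhibitor SFN (2.56 ± 0.15). In vehicle-treated HCC70, CLIC6, IL7R, CDK15 and CRLF2 were at 3.94, 3.56, 3.97 and 4.49, below the lower quartile there (4.80 to 4.83), and LAPTM5 was at 5.19, whereas SFN was at 11.48. In JQ1-treated MDA-MB-231, IL7R, CDK15 and CRLF2 were below the lower quartile as well, at 3.63, 4.46 and 4.62. Low signals thus limited the falls of these genes seen in both lines. Their differences are bounds in neither direction and are read without an order.

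**Figure D4:**
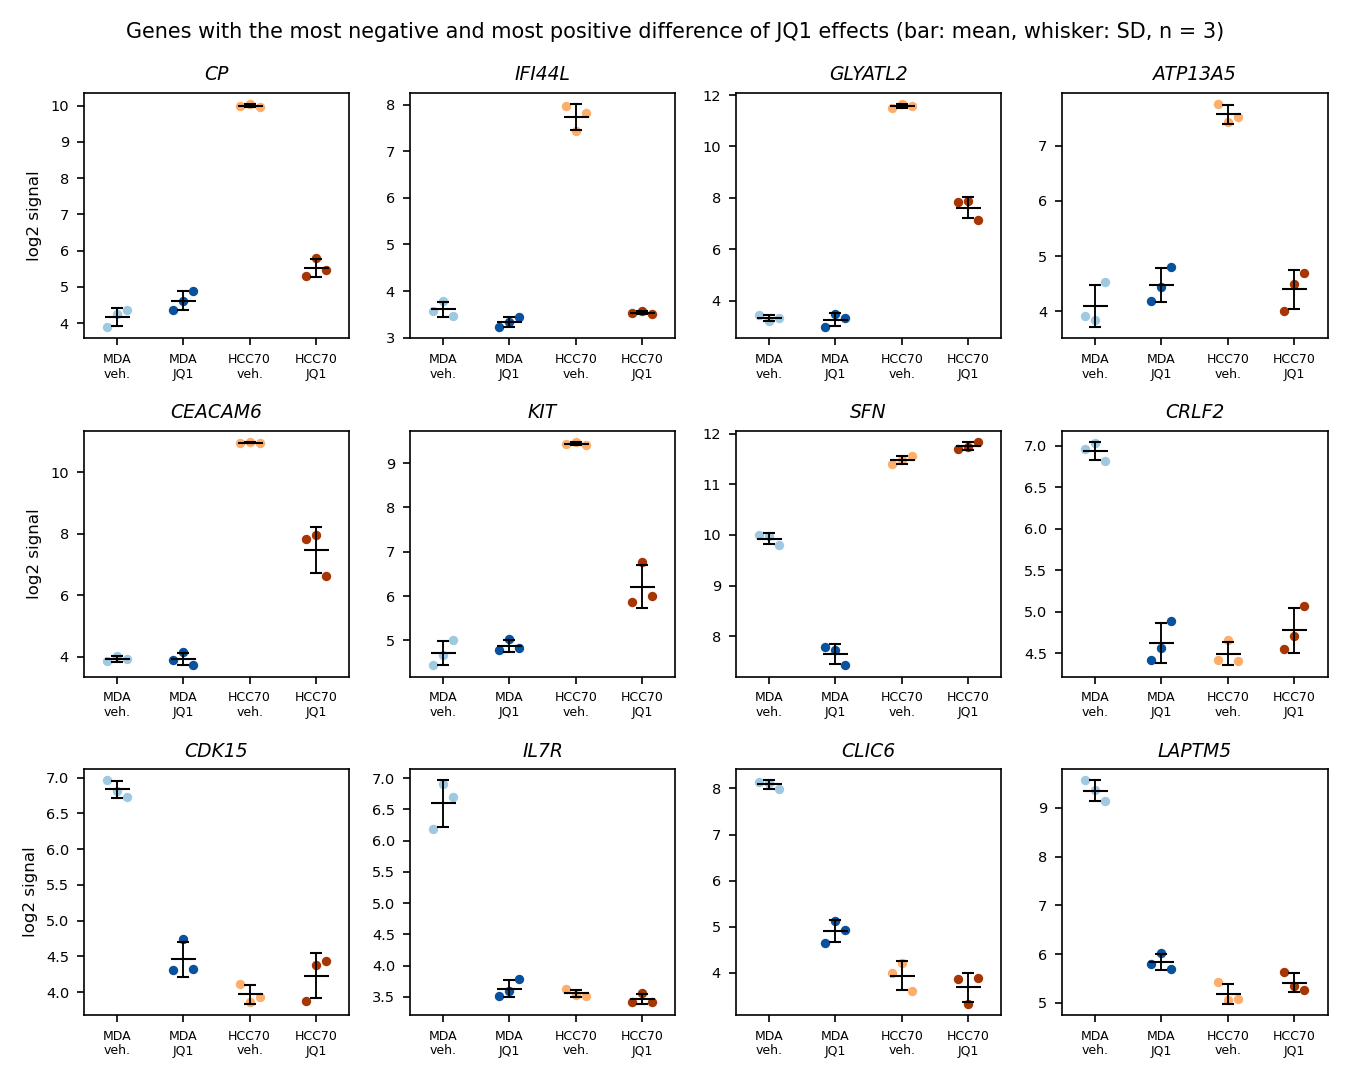
Log2 signal on each array for the 6 genes with the most negative and the 6 with the most positive difference of the JQ1 effects, by group (veh., vehicle; points, single arrays; bar and whisker, mean and SD, n = 3). CP was at 5.52 in JQ1-treated HCC70, below vehicle by a log2 change of -4.49, and at 4.16 and 4.62 in MDA-MB-231, while LAPTM5 fell from 9.35 to 5.84 in MDA-MB-231 and was at 5.19 and 5.42 in HCC70.

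Of the fixed readouts, AURKA, AURKB, FOXM1 and MYBL2 fell further in MDA-MB-231, with differences of 1.29 ± 0.13, 1.55 ± 0.12, 1.02 ± 0.14 and 1.62 ± 0.14. FOSL1 fell in MDA-MB-231, its change in HCC70 did not pass (0.13 ± 0.15), and the difference was 1.60 ± 0.21. In vehicle FOSL1 was at 5.6 to 6.1 in HCC70, below the median of the genes there, against 10.5 to 10.6 in MDA-MB-231. Less room to fall in HCC70 was therefore not told apart from a smaller effect on FOSL1 there. MYC fell further in HCC70, by -0.50 ± 0.14 (limma adjusted p = 0.030), a call that ended with the replicate number as a block (adjusted p = 0.073). It also ended without the 3 arrays numbered 3 (adjusted p = 0.078), without MDA-MB-231 vehicle replicate 1 or 2 or JQ1 replicate 1, and without HCC70 vehicle replicate 2 or 3 or JQ1 replicate 3 (adjusted p = 0.058 to 0.079). The differences of BRD2 (0.35), HEXIM1 (0.52), LIN9 (0.31) and BRD3 did not pass. Camera called 14 of 33 lists for this difference, and with an estimated correlation it called 0, where 9 had an unadjusted p under 0.05; fry called 23.

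All 35 mitotic genes fell further in MDA-MB-231, over all genes and adjusted over the list alone, with a median difference of 1.45. For the mitotic difference camera gave adjusted p = 2.5e-40, and adjusted p = 0.064 with an estimated correlation. The differences were 2.04 ± 0.12 for CDC20, an activator of the anaphase-promoting complex, and 1.63 ± 0.11 for TOP2A. For DNA replication and nucleotide synthesis 21 of 25 differences were positive, 22 adjusted over the list alone, with a median of 1.14. For the replication difference camera gave adjusted p = 2.9e-20, and adjusted p = 0.10 with an estimated correlation. For homologous recombination and Fanconi repair 9 of 12 were positive, 11 adjusted over the list alone. For the repair difference camera gave adjusted p = 7.0e-09, and adjusted p = 0.10 with an estimated correlation. In the list of G1 cyclins, CDKs and E2F genes 11 of 17 differences were positive and 2, E2F2 and CCND1, negative, also adjusted over the list alone. For the G1 difference camera gave adjusted p = 6.0e-05, and adjusted p = 0.13 with an estimated correlation. MuvB, B-MYB and FOXM1 regulators had 5 of 13 positive differences, 7 adjusted over the list alone. For the MuvB difference camera gave adjusted p = 0.00021, and adjusted p = 0.30 with an estimated correlation. Ribosome biogenesis genes had positive differences in 9 of 23 cases, 9 adjusted over the list alone. For the ribosome difference camera gave adjusted p = 0.0010, and adjusted p = 0.30 with an estimated correlation.

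AP-1 and immediate early genes had 12 of 20 positive differences and 0 negative by limma, and 13 and 1 adjusted over the list alone, with a median of 0.64. For the AP-1 difference camera gave adjusted p = 3.9e-06, and adjusted p = 0.078 with an estimated correlation. Fatty acid synthesis genes had 7 of 15 positive and 1 negative, 9 and 1 adjusted over the list alone. For the fatty-acid difference camera gave adjusted p = 0.00012, and adjusted p = 0.16 with an estimated correlation. The difference was 1.33 ± 0.12 for FASN, which fell in MDA-MB-231 and rose by 0.34 ± 0.087 in HCC70 (a call that ended without HCC70 JQ1 replicate 2 or vehicle replicate 1, adjusted p = 0.062 and 0.061), and 1.13 ± 0.11 for SCD. Cholesterol synthesis and uptake genes had 5 of 17 positive differences, 5 adjusted over the list alone. For the cholesterol difference camera gave adjusted p = 0.0030, and adjusted p = 0.30 with an estimated correlation and 0.068 among genes above the median level. CDK inhibitors and p53 target genes had 3 of 9 positive, 7 adjusted over the list alone. For the p53 difference camera gave adjusted p = 0.0085, and adjusted p = 0.10 with an estimated correlation and 0.081 among genes above the median level. Genes of the unfolded protein response and amino acid stress had 7 of 16 positive with 2 negative, 9 and 4 adjusted over the list alone. For the stress difference camera gave adjusted p = 0.021, and adjusted p = 0.30 with an estimated correlation, 0.19 among genes above the median level and 0.051 without the 3 arrays numbered 3. Interferon response genes fell further in HCC70, with 11 of 27 differences negative and 4 positive, 12 and 4 adjusted over the list alone, and a median of -0.26. Most genes of this list were also higher in vehicle-treated HCC70, and IFI44L lay below the lower quartile in vehicle-treated MDA-MB-231. Less room to fall in MDA-MB-231 was therefore not told apart from a smaller effect there. For the interferon difference camera gave adjusted p = 0.00017, and adjusted p = 0.11 with an estimated correlation. SAMD9L differed by -1.87 ± 0.14 and ISG15 by 0.62 ± 0.15, the latter a call that ended without the 3 arrays numbered 3 (adjusted p = 0.068). Luminal genes had 6 of 21 negative differences and 2 positive, also adjusted over the list alone. For the luminal difference camera gave adjusted p = 0.0059, and adjusted p = 0.10 with an estimated correlation and 0.19 among genes above the median level. Basal keratinocyte-type genes had 5 of 11 negative and 1, SFN, positive, 6 and 2 adjusted over the list alone. Most luminal and basal genes were likewise higher in vehicle-treated HCC70, so the same limit holds for both lists. For the basal difference camera gave adjusted p = 0.040, and adjusted p = 0.32 with an estimated correlation. The basal list's call ended without MDA-MB-231 vehicle replicate 2 or JQ1 replicate 3, or without HCC70 vehicle replicate 1 or 2 or JQ1 replicate 2 or 3 (adjusted p = 0.054 to 0.10). It also ended without the 3 arrays numbered 3 (adjusted p = 0.11), among genes above the median level (0.69), with quantile normalization (0.067) and with fry (0.16).

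Some genes were called in opposite directions. The immune checkpoint ligand CD274 fell by 1.93 ± 0.11 in MDA-MB-231 and rose by 0.49 ± 0.11 in HCC70, and INSIG1 fell by 1.42 ± 0.086 and rose by 0.60 ± 0.086. The matricellular protein THBS1 fell by 0.72 ± 0.076 and rose by 0.88 ± 0.076, the MYB family member MYBL1 fell by 0.58 ± 0.094 and rose by 0.90 ± 0.094, and the stress factor DDIT3 fell by 0.88 ± 0.16 and rose by 0.58 ± 0.16. The replication licensing factor CDC6 fell by 1.06 ± 0.11 and rose by 0.40 ± 0.11. The call of DDIT3 in HCC70 ended without JQ1 replicate 1 or 2 or vehicle replicate 1 or 3 (limma adjusted p = 0.069 to 0.088). DDIT3 was at 4.73 in vehicle-treated HCC70, below the lower quartile of the genes there, so its rise is read as a lower bound. SUSD2, chosen after its values were seen, rose by 1.76 ± 0.12 in MDA-MB-231 and fell by 1.35 ± 0.12 in HCC70.

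The last comparison set the vehicle-treated lines against each other, as the background to the JQ1 effects. All 18 epithelial and 10 of 11 basal keratinocyte-type genes were higher in HCC70, and 13 of 16 mesenchymal genes were higher in MDA-MB-231. Camera called these 3 lists, and with an estimated correlation the adjusted p was 0.0012 for epithelial, 0.0040 for mesenchymal and 0.085 for basal genes. The largest differences were those of GLYATL2 (log2 8.27 ± 0.18 SE higher in HCC70), the secreted protease inhibitor SLPI (8.25 ± 0.16), RARRES1 (7.85 ± 0.18), CEACAM6 (7.04 ± 0.26) and MXRA5 (6.85 ± 0.16) in one direction, and of the ectoenzyme ENPP1 (-7.16 ± 0.11), the receptor kinase AXL (-6.86 ± 0.11), EDIL3 (-6.62 ± 0.18), IGFBP7 (-6.57 ± 0.12) and EMP3 (-6.01 ± 0.081) in the other. In the lower line GLYATL2, SLPI, RARRES1, CEACAM6, MXRA5, ENPP1 and EDIL3 lay at 3.32, 4.41, 4.17, 3.93, 4.64, 3.45 and 4.60, below the lower quartile of the genes on those arrays, so their differences are read as lower bounds without an order. By limma with Benjamini-Hochberg adjustment 7000 of 14884 genes differed, 3540 higher in HCC70 and 3460 higher in MDA-MB-231, and 2205 differed by at least 1 on the log2 scale.

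All 18 measured epithelial genes were higher in HCC70, also adjusted over the list alone, with a median difference of 2.41. For epithelial genes camera gave adjusted p = 1.2e-12, and adjusted p = 0.0012 with an estimated correlation. Examples were the splicing regulator ESRP1 (6.52 ± 0.11) and the transcription factor GRHL2 (5.18 ± 0.10). Of 16 mesenchymal genes 13 were lower in HCC70 and 2 higher, also adjusted over the list alone, with a median of -2.33. For mesenchymal differences camera gave adjusted p = 8.6e-08, and adjusted p = 0.0040 with an estimated correlation. THBS1 differed by -4.00 ± 0.076. Hypoxia and glycolysis genes were lower in HCC70 in 15 of 17 cases and higher in 1, also adjusted over the list alone. For hypoxia genes camera gave adjusted p = 2.7e-06, and adjusted p = 0.021 with an estimated correlation. Luminal genes were higher in 12 of 21 and lower in 2, also adjusted over the list alone. For luminal differences camera gave adjusted p = 0.00060, and adjusted p = 0.040 with an estimated correlation. These 4 lists were the ones that held among 13 called. Of 11 basal keratinocyte-type genes 10 were higher and 1 lower in HCC70, also adjusted over the list alone. For basal differences camera gave adjusted p = 2.3e-05, and adjusted p = 0.085 with an estimated correlation. The desmosomal cadherin DSC3 differed by 6.26 ± 0.15. Of 14 YAP and TEAD target genes 9 were lower and 1 higher, 11 and 1 adjusted over the list alone. For YAP differences camera gave adjusted p = 1.3e-05, and adjusted p = 0.067 with an estimated correlation. ANKRD1 differed by -5.93 ± 0.092. In the lower line ESRP1, GRHL2, DSC3 and ANKRD1 lay below the lower quartile of the genes, at 4.56, 4.72, 4.15 and 4.66, so these differences are read as bounds. Interferon response genes were higher in 15 of 27 and lower in 3, also adjusted over the list alone. For interferon differences camera gave adjusted p = 0.0016, and adjusted p = 0.19 with an estimated correlation. IFI44L was at 7.74 in HCC70 and 3.61 in MDA-MB-231. Cytosolic ribosomal proteins were lower in HCC70 in 16 of 23 cases and higher in 2, also adjusted over the list alone, with camera adjusted p = 0.00011, and adjusted p = 0.20 with an estimated correlation. Cholesterol synthesis and uptake genes were higher in 13 of 17 and lower in 1, 13 and 2 adjusted over the list alone, with camera adjusted p = 0.00033, and adjusted p = 0.22 with an estimated correlation. DNA replication and nucleotide synthesis genes were higher in 16 of 25 and lower in 6, 17 and 6 adjusted over the list alone, with camera adjusted p = 0.0099, and adjusted p = 0.72 with an estimated correlation. AP-1 and immediate early genes were lower in HCC70 in 11 of 20 cases and higher in 2, 11 and 3 adjusted over the list alone, with camera adjusted p = 0.0036, and adjusted p = 0.18 with an estimated correlation. Lysosome and autophagy genes were lower in 13 of 25 and higher in 2, also adjusted over the list alone, with camera adjusted p = 0.0036, and adjusted p = 0.26 with an estimated correlation. MuvB, B-MYB and FOXM1 regulators were higher in 9 of 13 and lower in 3, also adjusted over the list alone, with camera adjusted p = 0.033, and adjusted p = 0.70 with an estimated correlation.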

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

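Among the tests below, that of an array-wide shift and that of a run shared by both cell lines under number 3 were chosen only after the result was seen, and so was the use of level-matched lists in judging the state of proliferation, which the criterion set beforehand, random lists alone, would have left as a fitting explanation.

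The JQ1 effect differed between the lines (HCC70 minus MDA-MB-231, limma) for named genes and lists. The negative differences on the log2 scale were those of CP (-4.94), IFI44L (-3.93), GLYATL2 (-3.91), ATP13A5 (-3.55), CEACAM6 (-3.49), KIT (-3.40), CD180 (-3.37), ATOH8 (-2.77), EFR3B (-2.75), CALCR (-2.59), UCA1 (-2.42), CTSS (-2.16), IFITM1 (-1.90), DNM3 (-1.24), RFESD (-1.13), PEG10 (-0.63) and MYC (-0.50). Those of IFI44L, ATP13A5 and CD180 are bounds in neither direction, with levels below the lower quartile in JQ1-treated HCC70 and in vehicle-treated MDA-MB-231. The positive differences were those of TFPI2 (0.56), EPPK1 (0.83), FOXM1 (1.02), IQCN (1.03), CCN2 (1.13), ZNF10 (1.29), AURKA (1.29), AURKB (1.55), FOSL1 (1.60), MYBL2 (1.62), DEPDC1 (1.67), PCSK5 (1.82), PBK (1.84), RTKN2 (2.24), AMIGO3 (2.41), SFN (2.56), CRLF2 (2.60), CDK15 (2.64), IL7R (2.88), CLIC6 (2.94) and LAPTM5 (3.73). That of RTKN2 is a bound, with a JQ1 level in MDA-MB-231 below the lower quartile. Those of CRLF2, CDK15 and IL7R are bounds in neither direction, with levels below the lower quartile in JQ1-treated MDA-MB-231 and in vehicle-treated HCC70. In MDA-MB-231, CTSS under JQ1 (4.23 to 4.45) and EPPK1 in vehicle (4.68 to 4.72) also lay below the lower quartile. Their changes there are lower bounds, so the differences of CTSS and EPPK1 may be overstated in size. List medians differed by 1.45 for mitotic genes, 1.14 for DNA replication, 0.97 for homologous recombination, 0.87 for G1 cyclins, CDKs and E2F genes, 0.64 for AP-1, 0.48 for fatty acid synthesis, 0.46 for CDK inhibitors and p53 targets, 0.42 for the unfolded protein response, 0.35 for MuvB regulators, 0.33 for ribosome biogenesis, 0.31 for cholesterol synthesis, -0.18 for luminal, -0.26 for interferon response and -0.65 for basal keratinocyte-type genes. With an estimated correlation camera called 0 of these 14 lists (smallest adjusted p = 0.064). The call of MYC ended with the replicate number as a block (adjusted p = 0.073), and without MDA-MB-231 vehicle replicate 1 or 2 or JQ1 replicate 1 or HCC70 vehicle replicate 2 or 3 or JQ1 replicate 3 (0.058 to 0.079). Outside the named genes, transcript clusters without a gene symbol were called as well, 4073 of 37519 in MDA-MB-231 (1963 higher and 2110 lower) and 2449 in HCC70 (1171 and 1278).

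Mitotic genes fell further in MDA-MB-231 than in HCC70, by a median of 1.45. A signal ceiling in HCC70 would spare members that were no brighter there in vehicle, but the median over these 17 of 35 genes was 1.495 (95% 1.29 to 1.63 in a bootstrap over genes). Bootstraps in this paragraph resample genes of the list, which are not independent replicates. Their intervals do not cover the spread between arrays. Leaving out any 1 array gave medians of 1.39 to 1.52, which argues against 1 unlike array. A shift of whole arrays would move all genes alike. Relative to the median over all other genes the list differed by 1.448 (95% 1.292 to 1.597 in a bootstrap over genes). In the values as deposited the median difference over all genes tested was already 0.000333. The subtraction could therefore not change the list's value, and this test decides nothing. A difference between the cell lines themselves remains open and may account for the pattern, but with 1 line on either side it was not tested.

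Replicate 3 stood apart from replicates 1 and 2 in MDA-MB-231 in both treatments, with deviations that correlated at 0.362 across genes. Of 498 genes that deviated by over 0.3, 374 lay below the median level and 132 (26.5%, against 7.38% of the genes tested) were microRNA genes. A run shared by both cell lines under number 3 stays open, since the deviation of the HCC70 JQ1 replicate 3 array correlated with that in MDA-MB-231 at 0.366 and only that of the HCC70 vehicle array, at 0.0169, did not go with it. A brightness-dependent bias (Spearman rho -0.256 across genes, between the bounds of 0.1 and 0.3) and a different state of proliferation cannot be told apart here either, since the mitotic list's median deviation, -0.073, lay outside the middle 95% of random lists (percentile 1.76) but inside that of level-matched ones (8.63). Without the 3 arrays numbered 3, chosen after the data were seen, JQ1 changed 3898 genes in MDA-MB-231 and 3253 in HCC70.

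Other splits of the 6 arrays of a comparison (for the difference of the effects, the 6 JQ1 arrays centred on their line's vehicle mean) give 10 divisions, too few for a share under 0.05 (the smallest is 0.1). In each, 1 of 10 splits, the real one, gave as many. For genes the real and highest other counts were 4139 and 0 in MDA-MB-231, 3229 and 0 in HCC70, 2228 and 0 for the difference of the effects, and 7000 and 0 between the vehicle-treated lines. For lists they were 12 and 10 in MDA-MB-231, 12 and 9 in HCC70, and 14 and 7 for the difference. The MDA-MB-231 split with 10 lists called 0 genes. Every other split mixes arrays of both groups, so a real difference between the groups enters the spread within them. Counts of 0 genes were therefore likely beforehand, and these splits cannot be read as support for the gene counts. Of the 4 splits that part all same-numbered arrays of MDA-MB-231, those other than the real one gave 0 genes. For genes called in the same direction in both lines 1 of 100 splits gave as many (1634, highest other 0). That share decides nothing beyond the splits of each line, since with 0 genes in every other split of either line the shared count was bound to be 0.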

How the results depend on the processing

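The fit without the 3 arrays numbered 3 was chosen after the data were seen; all other alternatives were planned. With a log2 change of at least 1, a stricter criterion by construction, the counts were 648 genes in MDA-MB-231, 380 in HCC70, 607 for the difference of the effects, 2205 between the vehicle-treated lines and 108 in the same direction in both lines. Over all transcript clusters, which tests more features, 7496, 4984 and 15776 clusters were called in MDA-MB-231, HCC70 and between the lines. Array weights gave 5110 genes in HCC70, with a weight of 4.69 for JQ1 replicate 2; the cause was not tested. The correlation of the effects across genes was 0.517 among genes above the median level, 0.342 over all clusters, 0.432 with quantile normalization, 0.408 with array weights, 0.380 without the 3 arrays numbered 3, and 0.393 to 0.433 with 1 array left out; the cause was not tested. Camera with an estimated correlation called 0 lists in MDA-MB-231, 1 in HCC70 and 0 for the difference (9, 5 and 9 at an unadjusted p under 0.05), and fry, which sets a list against no other genes, called 19, 21 and 23. Genes above the median level gave 10 lists in MDA-MB-231, 7 in HCC70 and 10 for the difference, with fewer genes tested. Leaving out 1 array gave 3355 to 4236 genes in MDA-MB-231, 2506 to 3359 in HCC70, 1748 to 2376 for the difference, 6383 to 7100 between the lines and 1312 to 1613 in the same direction, and 12, 10 to 15 and 13 to 16 lists; an arm with 2 arrays relied on the spread pooled by limma. In HCC70 same-numbered arrays correlated at -0.0588, 0.0147 and 0.0702. With the replicate block 4210, 3236, 2171 and 1599 genes were called in MDA-MB-231, HCC70, for the difference and in the same direction, and 93.0% and 92.4% of the genes called in MDA-MB-231 and HCC70 kept their call; it called 12 lists in MDA-MB-231, 9 in HCC70 (in place of 12, without the YAP, BET and luminal lists) and 14 for the difference. The block could not be estimated between the vehicle-treated lines and was not run there. Of 110 called named genes and list members in MDA-MB-231, 110 in HCC70, 90 for the difference and 121 between the lines, 100, 96, 80 and 116 kept their call in every alternative run, and 0 reversed. The signal of dim genes limits the differences seen: in vehicle-treated MDA-MB-231 GLYATL2 was at 3.32, below the lower quartile of the genes.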

Other observations

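The gene families grouped by symbol below were chosen after the data were seen, and the criteria of the tests of genes enriched in a line were written before their results were seen.

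Lists that camera did not call held single genes with large changes. In the hypoxia and glycolysis list VEGFA, which encodes an angiogenic growth factor, fell by 2.11 ± 0.098 in MDA-MB-231 and by 0.70 ± 0.098 in HCC70, and the mitophagy receptor BNIP3 rose by 1.29 ± 0.093 in HCC70. In that list 2 of 17 genes rose and 2 fell in MDA-MB-231, and 8 and 3 in HCC70, with the same counts adjusted over the list alone (camera adjusted p = 0.53 and 0.085). Among receptor tyrosine kinases and ligands 4 of 27 genes rose and 7 fell in MDA-MB-231, and 3 and 7 in HCC70, also adjusted over the list alone (camera adjusted p = 0.92 and 0.50). EREG, an EGF receptor ligand, fell by 2.66 ± 0.16 in MDA-MB-231, and IGFBP5 and IGFBP3 fell by 1.94 ± 0.11 and 1.80 ± 0.18 in HCC70. Of 12 collagen and matrix genes 1 rose and 2 fell in MDA-MB-231, and 1 and 3 in HCC70, where 2 and 3 did adjusted over the list alone (camera adjusted p = 0.92 and 0.69). The proteoglycan gene HSPG2 rose by 1.63 ± 0.077 in MDA-MB-231 and TNC fell by 3.07 ± 0.11 in HCC70. The Notch target HEY2 fell by 2.28 ± 0.14 in HCC70, where 4 of 25 Notch and WNT pathway genes rose and 4 fell, against 2 and 5 in MDA-MB-231, also adjusted over the list alone (camera adjusted p = 0.93 and 0.94). Of 17 BCL2 family and apoptosis regulators 1 rose and 4 fell in MDA-MB-231 and 2 rose and 1 fell in HCC70, and 2 and 5 and 3 and 1 adjusted over the list alone (camera adjusted p = 0.60 and 0.94). The pro-apoptotic BCL2L11 rose by 1.27 ± 0.11 and 0.56 ± 0.11 and the caspase-8 regulator CFLAR changed by -1.25 ± 0.093 in HCC70.

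Of 11 MYC network genes 2 rose and 3 fell in MDA-MB-231 and 2 rose and 2 fell in HCC70, where 3 rose adjusted over the list alone (camera adjusted p = 0.996 and 0.98). The MYC antagonist MXD1 rose by 0.74 ± 0.095 and 0.65 ± 0.095. Few cytosolic ribosomal protein genes changed, 1 of 23 rising and 1 falling in MDA-MB-231 and 1 and 2 in HCC70, with 1 and 0 and 1 and 1 adjusted over the list alone (camera adjusted p = 0.92 and 0.080). Epithelial genes fell in 4 of 18 cases in MDA-MB-231, EPCAM by 1.74 ± 0.12, and 1 of 18 rose in HCC70, also adjusted over the list alone (camera adjusted p = 0.60 and 0.55). Of 9 CDK inhibitors and p53 targets 3 fell in MDA-MB-231 and 4 rose in HCC70, also adjusted over the list alone (camera adjusted p = 0.45 and 0.14). Of 10 oxidative phosphorylation genes 2 and 1 fell, also adjusted over the list alone (0.60 and 0.94). Of 3 antigen presentation genes 2 fell in MDA-MB-231 and 1 rose and 1 fell in HCC70, also adjusted over the list alone (0.090 and 0.94). Of 6 reference genes 1 rose and 1 fell in MDA-MB-231 and 1 fell in HCC70, where 1 also rose adjusted over the list alone (0.92 and 0.81). Of 9 families grouped by symbol, camera called 2 in MDA-MB-231 and 1 in HCC70. In MDA-MB-231 14 of 17 centromere protein (CENP) genes fell, with a median of -0.93 (camera adjusted p = 3.1e-10, and adjusted p = 0.039 with an estimated correlation), and 5 of 17 in HCC70 (camera adjusted p = 0.070). Of 40 kinesin (KIF) genes 20 fell and 6 rose in MDA-MB-231 (camera adjusted p = 0.00028, and adjusted p = 0.075 with an estimated correlation), and 14 fell and 4 rose in HCC70 (camera adjusted p = 0.21). The mitotic list also names CENP and KIF genes, so these families add no separate support to its fall. Their adjustment ran over 9 families and that of the mitotic list over 33 lists, so the adjusted p-values are not comparable. Of 10 toll-like receptor (TLR) genes 4 fell in HCC70 (camera adjusted p = 0.044, and adjusted p = 0.48 with an estimated correlation). In MDA-MB-231, of 1098 microRNA genes 67 rose and 40 fell (median 0.06; camera adjusted p = 0.11, which did not pass, and adjusted p = 0.039 with an estimated correlation, which did), and 26 rose and 25 fell in HCC70 (camera adjusted p = 0.61, and adjusted p = 0.56 with an estimated correlation). MicroRNA genes also made up 26.5% of the genes that deviated on the replicate 3 arrays of MDA-MB-231, against 7.38% of the genes tested.

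A hypothesis was that genes enriched in a line over the other fell there under JQ1. In MDA-MB-231 the median change of 291 enriched genes was -0.34, against -0.07 over level-matched lists (middle 95% -0.11 to -0.02). Of these 131 were called lower and 34 higher, and their median in HCC70 was 0.01. In HCC70 the median of 362 enriched genes was -0.42, against 0.01 (middle 95% -0.03 to 0.04), with 175 lower and 31 higher, and a median of 0.02 in MDA-MB-231. Enriched genes were chosen as lower in the other line, which left them less room to fall there. Their medians in the other line therefore cannot show that the fall was particular to a line. Level of expression alone is argued against as far as these lists go, since both medians lay at percentile 0 of the level-matched lists. The matched lists drew genes independently, although genes are not independent replicates. Their percentiles cover neither genes that change together nor the spread between arrays. Vehicle arrays shared by the choice and the test are argued against as well. With separate vehicle arrays the difference from the matched lists was 0.822 of its size in MDA-MB-231 and 0.986 in HCC70. The pattern may be biological, as a hypothesis tested on these data alone.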
